A study of Mus musculus with 12 samples.

How the data were processed

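Microglial RNA from Tmem119-Cre RiboTag mice was studied in 12 spinal cord libraries of female C57BL/6 mice with EAE, 6 labelled Kdm6a cKO (replicates 1 to 6) and 6 labelled WT (replicates 7 to 12). Per the labels, RNA was isolated with the Direct-zol kit and libraries were made with a stranded mRNA kit (KAPA). The authors' processing notes name bcl2fastq 2.17, FastQC and Trimmomatic and the genome build mm10. The aligner, the counting tool, the strand setting and the annotation release are not given in the sources used here. The authors deposited 1 table of raw read counts, with whole-number counts for 39017 Ensembl gene IDs in 12 columns, 1 per library. Of these IDs, 37607 had a symbol in the GENCODE annotation of mm10, which also gave the coordinates.

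Totals per library ran from 19040115 to 26296071 counts, and 3 counts corresponded to 0.114 to 0.158 CPM per library. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries was a duplicate (lowest chi-square per degree of freedom 24.6). The labels do not say that each library came from a separate animal, so p-values measure the spread between these libraries. The labels give no batch, and replicate numbers are not shared between the groups, so no pairing or block was used.

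Genes were filtered with filterByExpr at its defaults, which left 15015, and scaled by TMM. The groups were compared with the edgeR 4.0.16 quasi-likelihood test (robust) in R 4.3.3, with a Benjamini-Hochberg adjusted p under 0.05. Fold changes are cKO over WT, and the SE is the size of the log2 fold change divided by the square root of F. The biological coefficient of variation was 0.249 and the median log2 fold change of all genes 0.03 (0.04 with RLE scaling). Tested on simulated data of the same depth with 14870 genes, the test recovered 10.4%, 61.2% and 97.0% of genes changed 1.5-fold, 2-fold and 4-fold, and 5.88% of its calls were false, against 19.8% for DESeq2. The simulated genes were independent of each other and had the same dispersion in both groups. The real cKO libraries lay farther apart than the WT libraries, so these rates may not hold for this comparison or rank the tools in it.

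The comparison, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule takes Kdm6a, Kdm6b and Uty, the 12 genes with the largest rise and the 12 with the largest fall among called genes with a mean of at least 5 CPM and an established symbol, the 5 of smallest p, and from each list up to 4 measured members of smallest p. In the lists of homeostatic and disease-associated microglia it also takes the first 4 members as written. The list members named in the text are a subset of those the rule takes, chosen after their values had been seen.

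The 39 lists name 898 genes, of which 896 had a symbol in the table and 774 were tested, and 34 lists had at least 5 tested members. They cover homeostatic and disease-associated microglia, cholesterol synthesis, LXR targets and lipid efflux, lysosome and phagocytosis, type I interferon response, complement, MHC classes I and II, inflammatory cytokines and alternative activation. They also cover TGF-beta signalling, cell cycle, glycolysis and hypoxia, nuclear and mitochondrial oxidative phosphorylation subunits, ribosomal proteins, proteasome, unfolded protein response, immediate-early and stress genes, Kdm6 enzymes with Polycomb and COMPASS partners, genes that escape X inactivation, Y-linked genes and the RiboTag and Cre loci. The others mark neurons, astrocytes, oligodendrocytes and their precursors, Schwann cells, ependymal, endothelial and mural cells, border macrophages, monocytes, dendritic cells, T and NK cells, B and plasma cells, neutrophils, and erythroid cells with platelets. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with an estimated correlation and fry beside it. For each list, the mean log2 CPM per library was compared by an exact two-sided permutation test over all 924 assignments, whose smallest p is 0.00216, and adjusted over the 12 other-cell lists or over all 34.

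Alternative settings fixed in advance were RLE scaling, DESeq2 1.42.0, limma-voom with sample weights, no filter, and a mean of at least 5 CPM. So were the CNS marker component as a covariate, 1 surrogate variable (sva 3.50.0), the omission of each library in turn, an estimated correlation and fry. The median in place of the mean of marker lists was also fixed in advance. The CNS marker component was the first principal component of the neuron, glia, Schwann, ependymal, endothelial and mural cell markers. It stood at 1.55, 2.05 and 1.15 in cKO 1, 2 and 4, and at most at -0.15 in every other library. It thus goes in part with the genotype, and fits with it cannot fully separate the 2. Added after the data had been seen were fits without cKO 1 and cKO 2, limma-voom with weights per group, library totals with Apoe left out, and the permutation test of means for all lists. Of the 462 ways to part the libraries 6 against 6, 100 were fitted, the real one included. Figures were drawn with matplotlib 3.10.9. No column was left out.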

Results

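Ribosome-bound RNA of microglia was sequenced from the spinal cord of female C57BL/6 mice with experimental autoimmune encephalomyelitis (EAE), an immune-driven model of multiple sclerosis. In RiboTag mice, Cre recombinase switches on a tagged form of the ribosomal protein Rpl22, so that RNA on the ribosomes of Cre-expressing cells can be pulled out of whole tissue. Cre was under the control of Tmem119, a gene of microglia. A total of 6 libraries were labelled as a conditional knockout of Kdm6a (cKO, replicates 1 to 6) and 6 as wild type (WT, replicates 7 to 12). Kdm6a is an X-linked gene for a demethylase that removes a repressive mark from histone H3. The comparison asks which microglial transcripts differ during EAE when Kdm6a is deleted in these cells. Total counts per library were 22048462 ± 2053021 in cKO and 22144735 ± 2118503 in WT (SD, n = 6 each), from 19040115 in cKO 1 to 26296071 in WT 7.

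The deleted gene itself was read at a low level, and its difference between the groups did not pass the test. Kdm6a (X: 18162575 to 18279936, mm10) stood at 3.24, 4.50, 2.61, 3.02, 1.59 and 1.78 CPM (counts relative to the TMM-scaled library total) in cKO 1 to 6. In WT 7 to 12 it stood at 3.58, 3.71, 3.35, 5.51, 6.19 and 4.87 CPM. The log2 fold change of cKO over WT was -0.70 ± 0.25 (SE, n = 6 each), with an adjusted p of 0.117 by the edgeR quasi-likelihood test and a p of 0.0281 by an exact two-sided permutation test of CPM alone. Raw counts of Kdm6a ran from 36 to 124 in cKO and from 65 to 130 in WT. Kdm6b, the autosomal relative of Kdm6a, had a log2 fold change of 0.52 ± 0.18 (adjusted p = 0.103, edgeR). Uty, the Y-linked relative, had 0 counts in all 12 libraries, where 3 counts would be 0.114 to 0.158 CPM per library. Counts covered the whole gene, so reads of exons left in place were included, and the library labelled cKO 2 lay within the WT range of Kdm6a, so its genotype was not checked by this gene. The first component of central nervous system (CNS), Schwann cell, endothelial and mural cell markers is called the CNS marker component. Kdm6a passed with it in the model (log2 fold change -1.26), with 1 surrogate variable (-0.91) and with limma-voom sample weights (-0.58). Its adjusted p ran from 0.00137 to 0.233 over the alternatives.

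The largest falls in the cKO libraries included Gpx3, Apoc4, Itgal, Siglec1 and Gpnmb. Gpx3, a secreted glutathione peroxidase, fell from 429 ± 128 CPM in WT to 17.9 ± 8.84 CPM in cKO (SD, n = 6 each), a log2 fold change of -4.59 ± 0.37 (SE). The apolipoprotein genes Apoc4 and Apoc1 lie beside Apoe on chromosome 7, and their log2 fold changes were -3.93 ± 0.61 and -2.69 ± 0.60. Siglec1, a sialic acid receptor of macrophages, fell by 3.06 ± 0.38. Itgal, the alpha chain of the leukocyte integrin LFA-1, fell by 3.48 ± 0.30. Gpnmb, a glycoprotein of phagocytes under lysosomal stress, fell from 3550 ± 954 to 481 ± 490 CPM (log2 fold change -2.88 ± 0.55).

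Another 6 of the 12 most reduced genes were the membrane protein Tmem154 (-4.03 ± 0.29), Saa3, an acute-phase protein (-3.14 ± 0.83), and P2ry2, a receptor for extracellular nucleotides (-3.03 ± 0.29), with Osgin1, Mcoln3 and Nlrc3. Osgin1, an oxidative stress response gene, fell by 2.76 ± 0.20, Mcoln3, an endosomal cation channel, by 2.66 ± 0.69, and Nlrc3, a regulator of innate signalling, by 2.54 ± 0.35. Adjusted p over the 12 ran from 1.26e-05 for Tmem154 and Osgin1 to 0.0428 for Saa3 (edgeR quasi-likelihood test). In all except Saa3 and Mcoln3, every cKO library lay below every WT library. The smallest p-values of all belonged to Fcrl1, an Fc receptor-like gene (-2.24 ± 0.15, adjusted p = 8.28e-06), Tmem154, Osgin1, the X-linked tetraspanin Tspan7 (-1.77 ± 0.14, adjusted p = 1.49e-05) and Gpx3 (adjusted p = 2.30e-05). Leaving out single libraries ended the calls of Saa3 and Mcoln3, which passed in 3 and 4 of the 12 such fits. Both were lost without cKO 1, 2 or 4 or WT 7, 8, 9 or 12, Saa3 also without cKO 3 or WT 11, and Mcoln3 also without WT 10. With the CNS marker component in the model, Saa3, Gpnmb, Apoc1 and Mcoln3 did not pass, with log2 fold changes of -2.31, -2.28, -2.19 and -2.09. Calls also ended with no filter on low counts for Saa3 (adjusted p = 0.108), Mcoln3 (0.0892) and Apoc1 (0.0545), and without cKO 1 and cKO 2 together for Saa3 (log2 fold change -2.69, adjusted p = 0.145) and Mcoln3 (-2.39, adjusted p = 0.107).

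Apoe, the main apolipoprotein of CNS lipid transport, took 11.9% ± 2.46 of all counts in WT and 3.41% ± 2.50 in cKO (SD, n = 6 each). Its log2 fold change was -1.94 ± 0.55 and did not pass across all genes (adjusted p = 0.0547, edgeR). Every cKO library lay below every WT library, which gave a p of 0.00216 in an exact two-sided permutation test of CPM, the smallest that 6 against 6 can give. Apoe passed without cKO 3, without cKO 4 or without cKO 5, by DESeq2, with both kinds of limma-voom weights and with a surrogate variable, and over the alternatives its log2 fold change ran from -2.56 to -1.44 and its adjusted p from 0.00284 to 0.219.

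Among the genes with the largest rises were Siglech, a lectin of microglia, Hpgd, which breaks down prostaglandins, and Dcstamp, a fusion protein of multinucleated phagocytes. On the log2 scale Siglech rose by 1.72 ± 0.25 (SE, n = 6 each), Hpgd by 1.82 ± 0.37 and Dcstamp by 2.88 ± 0.54. Madcam1, an adhesion molecule for lymphocyte homing, rose by 2.88 ± 0.65, and Khdrbs3, an RNA-binding splicing factor, by 2.72 ± 0.36. The secreted protease Klk8 rose by 1.75 ± 0.22 and Cnn2, an actin-binding calponin, by 1.79 ± 0.17. The other members of the 12 were Emp2 (1.88 ± 0.21), Zfp827 (1.88 ± 0.28), the integrin adaptor Bcar1 (1.61 ± 0.43), and Fgf11 (1.59 ± 0.29), with Lrba, a regulator of vesicle traffic, which rose from 11.3 ± 2.19 to 34.3 ± 25.5 CPM (SD). Adjusted p ran from 5.94e-05 for Cnn2 to 0.0442 for Lrba (edgeR quasi-likelihood test). Madcam1, Bcar1 and Lrba passed in 8, 4 and 3 of the 12 fits without 1 library. Madcam1 was lost without WT 7, 8, 9 or 11, Bcar1 and Lrba without cKO 1, 2 or 4 or WT 7, 8, 9, 11 or 12, and Lrba without WT 10. With no filter on low counts, none of the 3 passed (adjusted p = 0.0599 for Madcam1, 0.0873 for Bcar1 and 0.0986 for Lrba, edgeR), and Bcar1 and Lrba also did not pass with weights per group. Neither Hpgd, Bcar1 nor Lrba passed with the CNS marker component or without cKO 1 and cKO 2 together. Without those libraries their log2 fold changes were 1.57 ± 0.40, 1.28 ± 0.46 and 1.46 ± 0.48. With the component they were 1.09 ± 0.33, 0.58 ± 0.36 and 0.63 ± 0.38, and that of Fgf11, which still passed, was 0.86 ± 0.20. The median of the 12 was 1.80 in the fit of all libraries and 1.44 with the component. Lrba overlaps Mab21l2 and Gm3788 on the other strand.

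**Figure D1:**
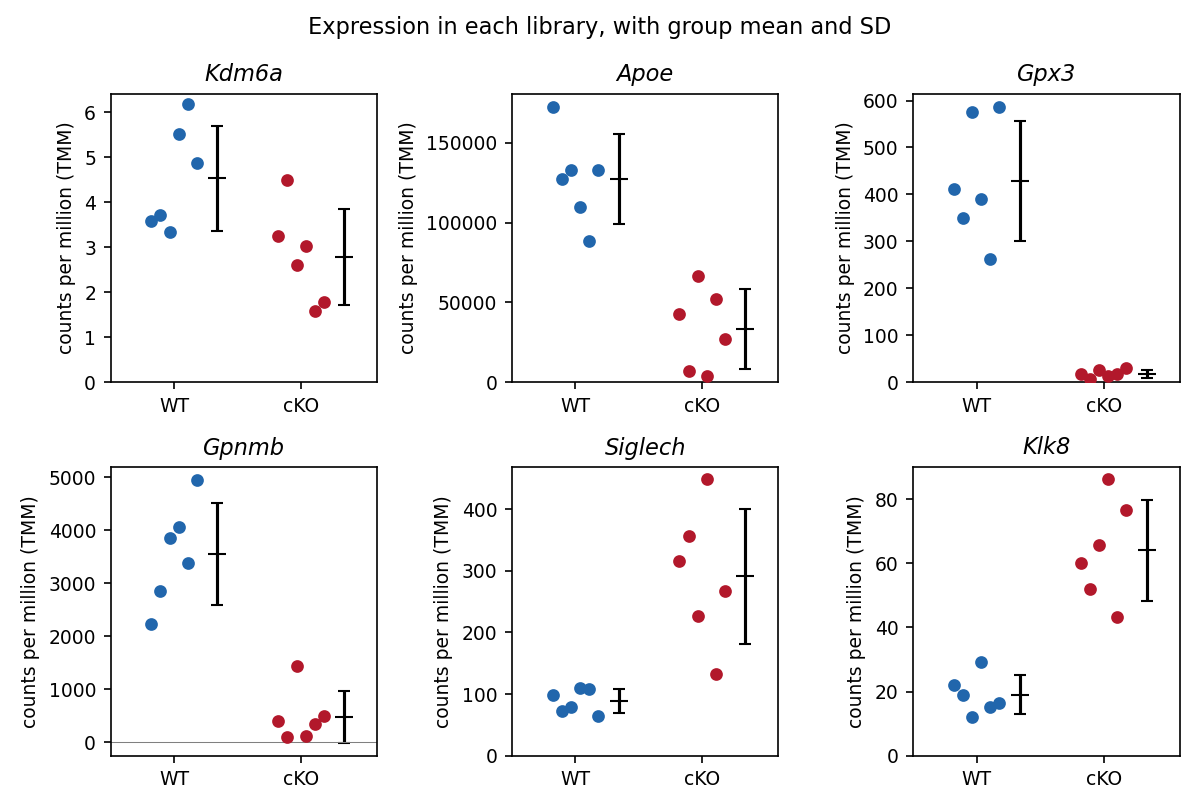
CPM (TMM-scaled, y axis) of Kdm6a, Apoe, Gpx3, Gpnmb, Siglech and Klk8 in each cKO and WT library, with the group mean ± SD (n = 6 each). Gpx3 averaged 17.9 CPM in cKO and 429 CPM in WT, while the Kdm6a values of the groups overlapped.

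**Figure D2:**
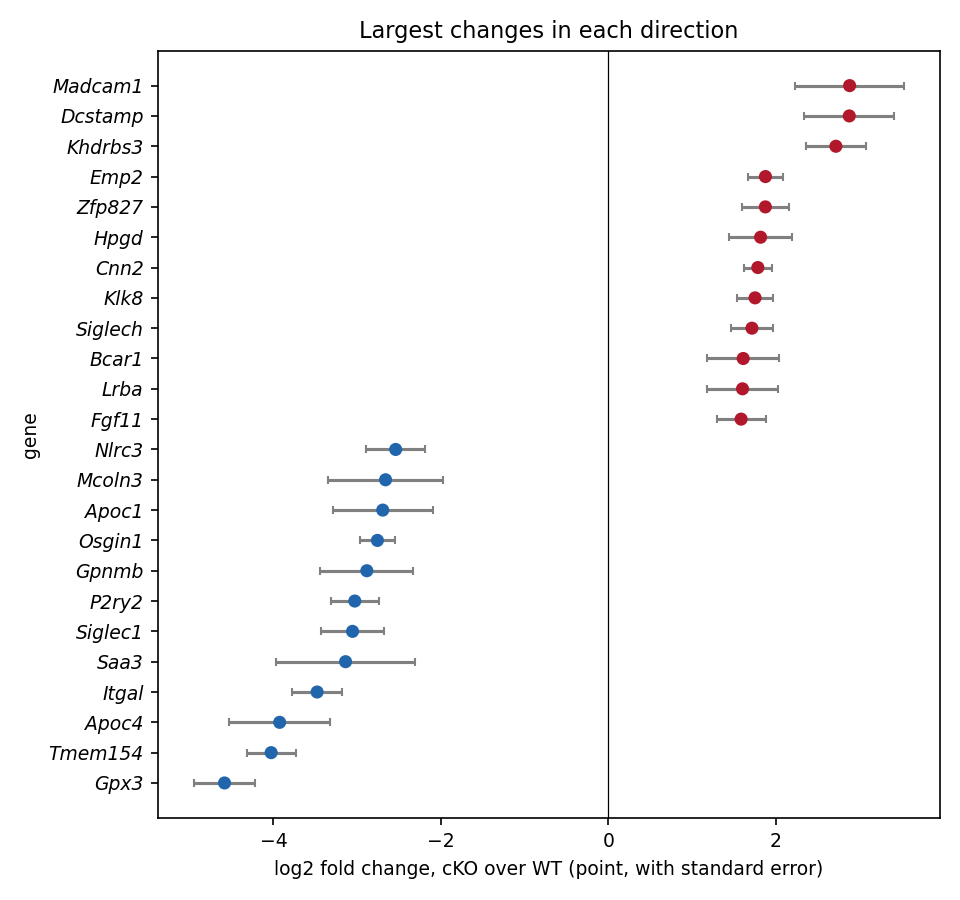
Log2 fold change of cKO over WT ± SE (n = 6 each) of the 12 genes with the largest fall and the 12 with the largest rise among called genes with a mean of at least 5 CPM. Values ran from -4.59 for Gpx3 to 2.88 for Madcam1.

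Of 15015 genes tested, 882 (5.87%) differed between cKO and WT at an adjusted p under 0.05, with 367 higher and 515 lower in cKO (edgeR quasi-likelihood test, Benjamini-Hochberg). At least 2-fold changes were seen in 151 of the higher and 203 of the lower genes. The groups did not overlap in 521 of the 882 genes and in 620 (4.13%) of all tested genes, where chance gives 0.216%. Libraries of the cKO group lay farther apart than those of WT, with a mean root-mean-square log2 distance of 0.677 against 0.435. The count was 416 without cKO 1 and cKO 2, the libraries with the most Schwann cell RNA, and 387 of these were among the 882. It was 966 with the CNS marker component in the model, and 500 of the 882 (56.7%) were among them. It moved to 2818 without cKO 5, 1410 without cKO 6, 518 without cKO 1, 545 without cKO 4, 575 without WT 8, 460 without WT 9, 532 without WT 11 and 470 without WT 12. It was 2385 with a surrogate variable, 1802 by DESeq2 and 4638 by limma-voom with sample weights.

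The mean of cholesterol synthesis genes was higher in cKO, and that of targets of LXR, the sterol-sensing receptor that drives lipid export, was lower, in an exact two-sided permutation test (adjusted p = 0.0368 and 0.0491). With an estimated correlation in camera neither list passed (adjusted p = 0.129 for cholesterol synthesis and 0.773 for LXR targets). Of 22 cholesterol synthesis genes measured, 9 rose and 13 did not pass (13 rose when adjusted over the list alone). The sterol carrier Stard4 rose by 0.99 ± 0.15 (SE, n = 6 each) and Cyp51, a lanosterol demethylase that overlaps Akap9 on the other strand, by 0.71 ± 0.12. Sqle, which makes squalene epoxide, rose from 5.60 ± 1.93 to 12.8 ± 2.89 CPM (SD). The mean log2 CPM of the list was 4.54 ± 0.07 in cKO and 4.11 ± 0.14 in WT (SD, n = 6 each). Of 17 LXR and lipid efflux genes, 4 fell and 13 did not pass (9 fell and 1 rose when adjusted over the list alone). Apoc1 was among the 4, with Mylip, which marks the LDL receptor for breakdown (-0.84 ± 0.15), Arl4c, a GTPase of cholesterol export (-0.66 ± 0.12), and Soat1, which esterifies cholesterol (-0.77 ± 0.21). The LXR list mean was 6.68 ± 0.47 in cKO and 7.40 ± 0.14 in WT.

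Both lists passed camera with its preset correlation (adjusted p = 3.92e-07 for cholesterol synthesis and 9.44e-05 for LXR targets). At that correlation both calls held in each of the 21 other fits, with adjusted p up to 0.000143 and 0.0279. With an estimated correlation neither held. Soat1 passed in 3 of the 12 fits without 1 library (those without cKO 3, 5 or 6). Its call also ended with RLE scaling, no filter, a minimum mean of 5 CPM, the CNS marker component and without cKO 1 and cKO 2 together (adjusted p from 0.00359 to 0.186 over the alternatives), and that of Apoc1 ended with no filter and with the CNS marker component. The log2 fold change of Soat1 was -0.64 ± 0.23 without those libraries. With the component the log2 fold changes were -0.48 ± 0.20 for Soat1 and -2.19 ± 0.74 for Apoc1. The lowest LXR means were those of cKO 2 (6.10) and cKO 4 (6.14), where neuron means were high (4.83 and 4.40). The LXR mean was 6.79 in cKO 1, with a neuron mean of 4.68, and 6.80 in cKO 5, with one of 3.69. Neuron means of cKO 5 and cKO 6 lay within the WT range, yet their LXR means (6.80 and 6.93) were below every WT library (lowest 7.17). That of cKO 3 (7.30) was within the WT range. Cholesterol synthesis was highest in cKO 5 (4.65). Without cKO 1 and cKO 2 the list differences were 0.43 for cholesterol synthesis and -0.61 for LXR targets.

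**Figure D3:**
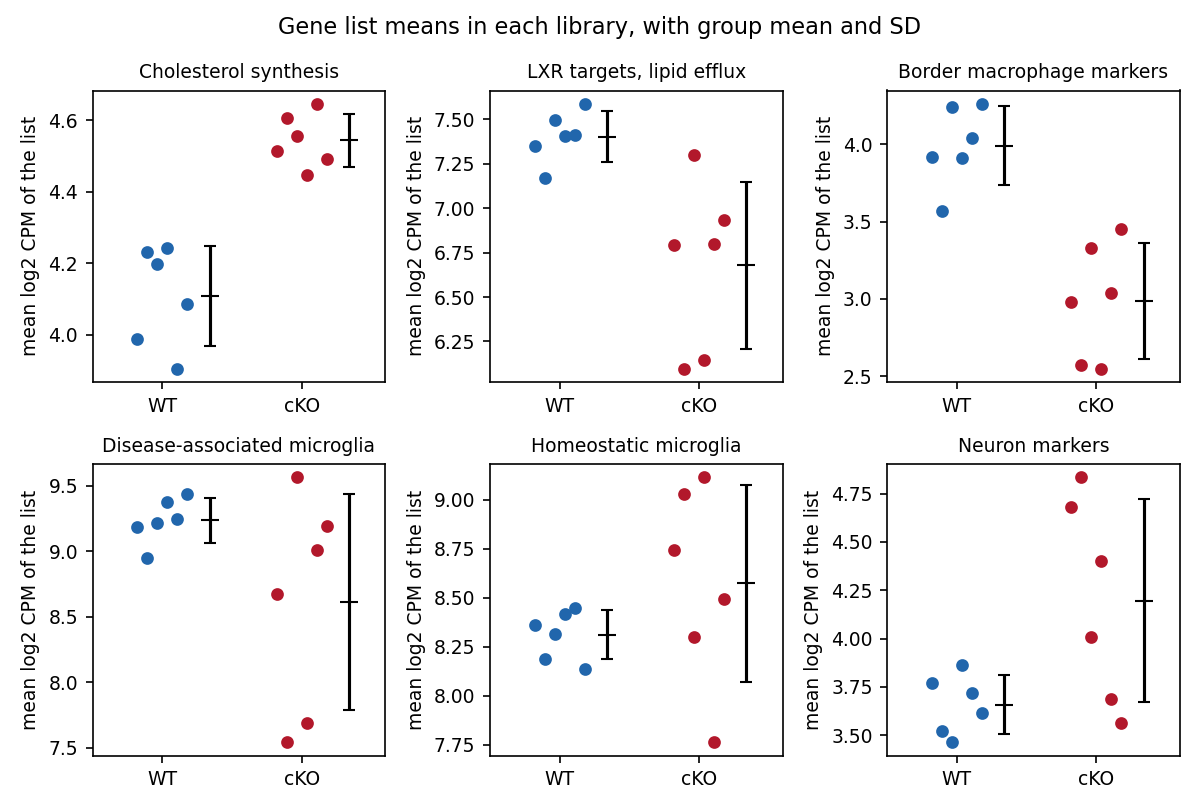
Mean log2 CPM (y axis) of the members of 6 gene lists in each cKO and WT library, with the group mean ± SD (n = 6 each). Cholesterol synthesis averaged 4.54 in cKO and 4.11 in WT, and the border macrophage list 2.99 and 3.99.

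Across all lists, 13 of the 34 tested passed camera with the preset correlation, 4 higher and 9 lower in cKO. None passed camera with an estimated correlation (smallest adjusted p = 0.129; 2 lists were under an unadjusted p of 0.05), fry passed 4 and the exact permutation test of list means passed 3. Those 3 were cholesterol synthesis, LXR targets and border macrophage markers.

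Of 37 genes of the disease-associated microglia signature, 3 fell and 34 did not pass (4 fell when adjusted over the list alone), and 5 of the 37 log2 fold changes were positive. The list passed camera (median -0.29, adjusted p = 4.26e-06) but not with an estimated correlation (adjusted p = 0.773) or in the exact permutation test of list means (p = 0.115, adjusted p = 0.357). Gpnmb was 1 of the 3, with Cd22, an inhibitory sialic acid receptor (-1.77 ± 0.35), and Cd68, a lysosomal protein of phagocytes (-0.93 ± 0.24). Trem2, a lipid receptor of microglia (-0.36 ± 0.18, adjusted p = 0.229), its adaptor Tyrobp (-0.27 ± 0.20, adjusted p = 0.458) and the lipase Lpl (-0.25 ± 0.45, adjusted p = 0.805) did not pass in edgeR. Of 47 lysosome and phagocytosis genes, 4 fell and 43 did not pass (5 fell when adjusted over the list alone). Among those that fell were Cd68, the lysosomal membrane protein Lamp1 (-0.57 ± 0.16) and Sgsh, a heparan sulfate-degrading enzyme (-0.85 ± 0.18).

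The median of the lysosome list was -0.34 (camera adjusted p = 1.48e-07), and its adjusted p was 0.773 with an estimated correlation. Disease-associated means were 7.54 in cKO 2, 7.69 in cKO 4, 8.67 in cKO 1 and 9.56 in cKO 3, the highest of all libraries. Those of cKO 5 (9.01) and cKO 6 (9.20) lay within the WT range of 8.95 to 9.43. Only cKO 1, cKO 2 and cKO 4 thus lay below every WT library. Neuron means in cKO 2, 4, 1 and 3 were 4.83, 4.40, 4.68 and 4.01, all above every WT library (at most 3.86). Those of cKO 5 (3.69) and cKO 6 (3.56) were within the WT range. With the CNS marker component in the model, the median of the disease-associated list was -0.01 and its call ended, with adjusted p from 1.46e-09 to 0.840 over the alternatives, while the lysosome list passed in all 21. The same fit ended the calls of Gpnmb, Cd22, Cd68 and Lamp1, with log2 fold changes of -2.28 ± 0.64, -1.37 ± 0.40, -0.64 ± 0.24 and -0.46 ± 0.17. Without cKO 1 and cKO 2 together, Cd68 (-0.78 ± 0.23) and Lamp1 (-0.49 ± 0.18) did not pass. Lamp1 also did not pass with no filter or a minimum mean of 5 CPM, nor did Sgsh with library totals without Apoe as the scaling. Cd68 and Lamp1 each passed in 3 of the 12 fits without 1 library (both were lost without cKO 1, 2 or 4 or any 1 of the WT libraries).

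Of 36 homeostatic microglial genes, 5 rose, 1 fell and 30 did not pass (8 rose and 2 fell when adjusted over the list alone), and 30 of the 36 log2 fold changes were positive. Siglech rose, as did Selplg, a selectin ligand (0.87 ± 0.21), and Olfml3, a secreted matrix protein (0.61 ± 0.15), while P2ry6, a nucleotide receptor of phagocytosis, fell by 0.44 ± 0.09. The nucleotide receptors P2ry12 (1.14 ± 0.43, adjusted p = 0.129) and P2ry13 (0.39 ± 0.25, adjusted p = 0.390), both inside Med12l, the fractalkine receptor Cx3cr1 (0.40 ± 0.22, adjusted p = 0.310) and Tmem119 (0.14 ± 0.25, adjusted p = 0.796) did not pass in edgeR. The list median was 0.39 and the camera adjusted p 0.00636, against an adjusted p of 0.829 with an estimated correlation. The list call ended without cKO 2, without cKO 4, without cKO 1 and cKO 2, and with the CNS marker component, where its median was -0.04. Its adjusted p ran from 5.29e-06 to 0.685 over the alternatives. Selplg and Olfml3 did not pass with the CNS marker component (0.43 ± 0.16 and 0.46 ± 0.15), and Selplg (0.67 ± 0.22), Olfml3 (0.56 ± 0.16) and P2ry6 (-0.40 ± 0.11) did not pass without cKO 1 and cKO 2 together. Selplg passed in 5 and Olfml3 in 4 of the 12 fits without 1 library (both were lost without cKO 2 or 4 or WT 8, 9, 11 or 12, Selplg also without cKO 1 and Olfml3 also without WT 7 or 10).

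Interferon and complement genes fell in part. Of 44 type I interferon response genes, 4 fell and 40 did not pass (5 fell when adjusted over the list alone). The 4 were the antiviral RNA sensors Oas3 (-2.21 ± 0.46) and Oas2 (-1.61 ± 0.40), the mitochondrial nucleotide kinase Cmpk2 (-0.83 ± 0.21) and the exonuclease Isg20 (-0.88 ± 0.23). Of 16 complement genes, 3 fell and 13 did not pass (3 fell and 1 rose when adjusted over the list alone). The 3 were the anaphylatoxin receptor C3ar1 (370 ± 31.6 CPM in WT, 185 ± 43.8 in cKO) and the classical pathway components C2 (-1.25 ± 0.26) and C4b (-1.15 ± 0.31). Medians were -0.29 for the interferon list (camera adjusted p = 2.12e-05, and adjusted p = 0.784 with an estimated correlation) and -0.18 for complement (camera adjusted p = 0.0455, and adjusted p = 0.773 with an estimated correlation). Both list calls ended with the CNS marker component, and that of complement also with a surrogate variable, a minimum mean of 5 CPM, weights per group, and without cKO 1 and cKO 2 together or any of cKO 1, 2, 4 or 5 or WT 8, 9 or 11. Adjusted p ran from 1.25e-09 to 0.297 for interferon and from 0.00779 to 0.897 for complement over the alternatives. With the CNS marker component, Oas3 (-1.90 ± 0.61), Oas2 (-1.44 ± 0.48), Cmpk2 (-0.72 ± 0.25), Isg20 (-0.72 ± 0.25), C2 (-1.03 ± 0.30) and C4b (-0.97 ± 0.41) did not pass. These folds were 82.4% to 89.4% of those without the component, while each SE was larger. Without cKO 1 and cKO 2 together, Oas2 (-1.33 ± 0.40), Cmpk2 (-0.79 ± 0.25), Isg20 (-0.76 ± 0.25) and C4b (-1.10 ± 0.36) did not pass. Calls also ended with weights per group for Cmpk2 and C4b, with library totals without Apoe for Isg20 and C4b, and with no filter or a surrogate variable for C4b. Oas2, Cmpk2, Isg20 and C4b passed in 6, 5, 4 and 4 of the 12 fits without 1 library. All 4 were lost without cKO 1 or 2 or WT 9, 11 or 12. Cmpk2, Isg20 and C4b were lost without cKO 4, Cmpk2 and C4b without cKO 3, Oas2, Isg20 and C4b without WT 8, and Isg20 without WT 7.

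Antigen presentation and ribosomal protein genes gave few calls. Of 20 MHC class I processing genes, 0 passed in edgeR, 4 were under an unadjusted p of 0.05, and 0 passed in DESeq2. The class I chains H2-D1 and H2-T23 had log2 fold changes of -0.44 ± 0.20 and -0.50 ± 0.21 (adjusted p = 0.194 and 0.173). The class I median was -0.13 (camera adjusted p = 0.0455, and adjusted p = 0.853 with an estimated correlation). Of 10 MHC class II genes, H2-Ob, which limits peptide loading, fell by 1.02 ± 0.20, and the other 9, such as H2-Eb1 (0.50 ± 0.36, adjusted p = 0.444), did not pass. The class II list did not pass either (median 0.26, camera adjusted p = 0.888). Of 66 ribosomal protein genes, 0 passed in edgeR, 9 were under an unadjusted p of 0.05, and 1 passed in DESeq2, with Rpl7 at -0.28 ± 0.09 and Rps9 at -0.41 ± 0.16 (adjusted p = 0.0828 and 0.129). The ribosomal median was -0.22 (camera adjusted p = 5.55e-05, and adjusted p = 0.784 with an estimated correlation), for genes whose reads are shared with many pseudogene copies. With the CNS marker component, the class I and ribosomal medians turned to 0.16 and 0.01 and neither list passed. The class I call was also lost with a surrogate variable, with a minimum mean of 5 CPM, without cKO 1 and cKO 2 together (median 0.07), and without any of cKO 1, 2, 3 or 4 or WT 8, 9 or 11. Over the alternatives, adjusted p ran from 0.000261 to 0.946 for class I and from 1.85e-10 to 0.897 for ribosomal proteins.

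Markers of border-associated macrophages, the macrophages of the meninges and perivascular spaces, were lower in cKO. The list mean was 2.99 ± 0.37 log2 CPM in cKO and 3.99 ± 0.26 in WT (SD, n = 6 each), with an exact two-sided permutation p of 0.00216 and an adjusted p of 0.0260 over the 12 lists of other cell types. Of its 8 measured genes, 2 fell, Siglec1 and the membrane protein Ms4a7 (-2.03 ± 0.51, SE), and 6 did not pass (3 fell when adjusted over the list alone). Among the 6 were the scavenger receptor Stab1 (-0.59 ± 0.18, adjusted p = 0.0640) and ceruloplasmin, Cp (-0.56 ± 0.28, adjusted p = 0.243). Camera gave an adjusted p of 0.00298, and an adjusted p of 0.129 with an estimated correlation. Without cKO 1 and cKO 2 the difference was -0.90, with an exact permutation p of 0.00476, the smallest that 4 against 6 can give. The adjusted p of the list mean was 0.0519 without cKO 4 and without WT 9, and Ms4a7 passed in 5 of the 12 fits without 1 library (lost without cKO 1 or 4 or WT 7, 9, 10, 11 or 12) and did not pass with the CNS marker component (-1.40 ± 0.51), with no filter or without cKO 1 and cKO 2 together (-1.71 ± 0.46).

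RNA of neurons, glia and nerve sheath was unevenly spread over the cKO libraries. Prx, which Schwann cells make, stood at 5.03 CPM in cKO 1 and 12.3 CPM in cKO 2 and at most at 0.988 CPM in the other libraries. Of 22 neuron markers, Uchl1, a neuronal deubiquitinase, rose by 0.56 ± 0.11 and 21 did not pass (16 rose when adjusted over the list alone), such as Gad1 (1.38 ± 0.39, adjusted p = 0.0562) and Slc32a1 (0.87 ± 0.26, adjusted p = 0.0609) of inhibitory neurons. The neuron mean was 0.54 higher in cKO (exact permutation p = 0.0433, adjusted p = 0.104) and 0.26 higher without cKO 1 and cKO 2 (p = 0.162). Of 16 astrocyte markers, 0 passed in edgeR, 6 were under an unadjusted p of 0.05 and 1 passed in DESeq2, with the glutamate transporter Slc1a2 at 0.84 ± 0.30 and the glycolytic enzyme Aldoc at 0.64 ± 0.18 (adjusted p = 0.113 and 0.0575). Camera called both lists higher (adjusted p = 1.41e-05 for neurons and 0.0446 for astrocytes), and each had an adjusted p of 0.773 with an estimated correlation. Astrocyte markers lost their call with a surrogate variable, with library totals without Apoe, without cKO 1 and cKO 2 together and without any of cKO 1, 2, 3 or 4 or WT 9, 11 or 12. Both lists lost it with the CNS marker component, and adjusted p ran from 1.66e-07 to 0.356 for neurons and from 0.000973 to 0.897 for astrocytes.

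Immune and vascular markers gave few calls per list. Of 8 T and NK cell markers, Klrb1c, an NK cell receptor, fell by 3.05 ± 0.38 and 7 did not pass, such as Cd4 (-1.05 ± 0.39, adjusted p = 0.120) and Cd3e (-0.86 ± 0.39, adjusted p = 0.200). Klrb1c was near the floor in cKO, at 0.167 ± 0.088 CPM against 1.39 ± 0.52 CPM in WT (SD), where 3 counts would be 0.114 to 0.158 CPM. In this list 1 of the 8 log2 fold changes was positive, and the median was -0.87. The T and NK mean differed by -0.74 (exact permutation p = 0.0173, adjusted p = 0.0519), and camera gave an adjusted p of 0.0181, against an adjusted p of 0.773 with an estimated correlation. Of 8 dendritic cell markers, 2 rose, Siglech and the actin bundler Fscn1 (1.58 ± 0.20), and 6 did not pass (3 rose and 2 fell when adjusted over the list alone). Among the 6 were the chemokine Ccl22 (1.40 ± 0.43, adjusted p = 0.0707) and Batf3, which went the other way (-0.54 ± 0.15, adjusted p = 0.0560, edgeR). Siglech is also a member of the homeostatic microglia list. The dendritic list mean was 0.52 higher (exact permutation p = 0.00866, adjusted p = 0.0519). Of 17 monocyte markers, the chemokine receptor Ccr1 rose by 1.64 ± 0.43 and Ms4a4c fell by 1.09 ± 0.25, with a mean difference of -0.17 (exact permutation p = 0.584). That difference was -0.05 without cKO 2 and -0.37 without cKO 5, and it turned to 0.12 without cKO 1 and cKO 2 together. Of 13 endothelial markers, the VEGF receptor Kdr fell by 1.21 ± 0.14 (mean difference 0.02, exact permutation p = 0.905). The 5 erythroid and platelet markers had a mean difference of 0.28 (exact permutation p = 0.0152, adjusted p = 0.0519). The dendritic mean passed with RLE scaling, without cKO 1 and cKO 2, and without cKO 1, 2 or 5 or WT 7, 8, 10, 11 or 12 (adjusted p from 0.0130 to 0.0909). The T and NK, neuron and oligodendrocyte precursor means passed without cKO 5 (adjusted p = 0.0468 for each), and the erythroid mean passed without WT 8 (adjusted p = 0.0433). The erythroid difference was 0.15 in the fit without WT 9, 0.18 without WT 12 and 0.18 without cKO 6. The filter on low counts was applied anew in each such fit, so the members averaged can change. These lower values therefore cannot be put down to the omitted libraries alone. Ccr1 passed in 3 and Ms4a4c in 8 of the 12 fits without 1 library (both were lost without cKO 1 or WT 8, 9 or 11, and Ccr1 also without cKO 2, 4 or 6 or WT 7 or 12). Neither gene passed with the CNS marker component (1.52 ± 0.51 for Ccr1 and -0.82 ± 0.26 for Ms4a4c) or without cKO 1 and cKO 2 together (97.8% and 80.3% of the log2 fold change left), and Ccr1 also did not pass with no filter or with weights per group. The camera call of T and NK markers was lost without WT 11, with the CNS marker component, with a surrogate variable and with weights per group (adjusted p from 0.00119 to 0.242 over the alternatives).

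The remaining marker lists gave no edgeR call among 21 oligodendrocyte, 9 oligodendrocyte precursor, 14 mural and fibroblast and 5 Schwann cell genes. In these 4 lists, 5, 4, 8 and 4 genes were under an unadjusted p of 0.05, and DESeq2 called 0, 0, 1 and 3. Mean differences were 0.16, 0.21, -0.38 and 0.62, with exact permutation p of 0.184, 0.134, 0.158 and 0.335. The Schwann cell difference was 0.27 without cKO 2 and turned to -0.14 without cKO 1 and cKO 2 together. The mural and fibroblast difference was -0.20 without cKO 4. Of 3 measured B and plasma cell genes, Ighm, the heavy chain of IgM, rose by 1.04 ± 0.17 (adjusted p = 0.00279, edgeR). None of 4 neutrophil and 3 ependymal genes passed in edgeR or DESeq2, and 1 of each was under an unadjusted p of 0.05; the neutrophil alarmin S100a8 had a log2 fold change of 1.31 ± 0.59 (adjusted p = 0.194). Y-linked genes had 0 to 4 counts per library, and none was tested.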

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

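The tests that leave out cKO 1 and cKO 2 and both tests of the spread among the cKO libraries were chosen only after the results had been seen, and the fit with library totals without Apoe after the data but before its own result; the test with CNS markers and the splits were planned.

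The 12 genes with the largest falls in cKO, such as Gpx3, Siglec1 and Gpnmb, had a median log2 fold change of -3.04. RNA of other cells in cKO 1 and cKO 2, which might dilute microglial RNA there, is argued against as the whole cause, since without those libraries the median was -2.71 and 10 of the 12 still passed. Carry-over of CNS and Schwann cell RNA in all libraries is argued against as the whole cause in the same way. With the CNS marker component in the model the median was -2.51 and 8 of the 12 passed. That component was built without markers of blood or immune cells, so it cannot measure carry-over of their RNA. The 12 genes were picked for their falls in the fit of all libraries, so both tests start from a chosen set. The calls of Saa3 (-3.14 ± 0.83 before, -2.31 ± 0.79 after), Gpnmb (-2.88 ± 0.55, then -2.28 ± 0.64), Apoc1 (-2.69 ± 0.60, then -2.19 ± 0.74) and Mcoln3 (-2.66 ± 0.69, then -2.09 ± 0.86) ended, because the folds shrank while their errors stayed about as large or grew, so part of their fall could go with that component. An effect of Kdm6a deletion on microglia stays open, as does a smaller contribution of border macrophages or of other immune cells. Border macrophage markers were lower in cKO, and no separate test was run on these genes for either source.

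The 12 genes with the largest rises had a median log2 fold change of 1.80 in all libraries and of 1.44 with the CNS marker component, with 9 of the 12 called, and Bcar1, Lrba and Fgf11 had 36.0%, 39.3% and 53.9% of their log2 fold change left.

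The second pattern is the number of genes and lists that differed between cKO and WT. Apoe took 11.9% of counts in WT and 3.41% in cKO, but with Apoe left out and library totals as the only scaling 683 of the 882 genes were still called, which argues against its share as the whole cause. Chance is argued against as the source of the whole gene count. Of 100 splits of the libraries, 1, the real one, gave as many as 882, and the highest other gave 0. The other splits mix the genotypes, so they do not show which single calls are free of chance. The count itself ran from 416 to 4638 over the alternatives. Chance cannot be excluded for the lists, since 35 of 100 splits gave 13 or more called lists by camera with the preset correlation, and the highest other gave 21. A difference in collection day or litter between the groups, which the labels do not give, stays open beside the genotype.

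The cKO libraries lay farther apart than the WT libraries, with a mean distance of 0.677 against 0.435, and 11 of the 15 cKO pairs were farther apart than every WT pair. Carry-over into cKO 1 and cKO 2 is argued against as the whole cause, since the other 4 cKO libraries still had a mean distance of 0.668, above the largest WT distance of 0.505. Depth is argued against too, since the highest and lowest cKO totals differed 1.31-fold. Uneven carry-over across all cKO libraries was not tested. Neuron means of cKO 3 and cKO 4 were also above every WT library (4.01 and 4.40), and cKO 4 and cKO 5 lay 0.885 apart. The libraries cKO 5 and cKO 6, with neuron means within the WT range, lay 0.589 apart, also above the largest WT distance of 0.505. The closest cKO pairs were cKO 1 and cKO 2 (0.437) and cKO 2 and cKO 4 (0.443), all with high neuron means. The farthest pairs both held cKO 5, with cKO 2 (1.06) and with cKO 1 (0.921). Uneven carry-over across the cKO libraries stays open, as do uneven deletion of Kdm6a, uneven disease and uneven pulldown between them, none of which was tested.

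Among 282 sets of 6 libraries checked for a single library far from the rest, 8 (2.84%) stood out, where chance gives about 1 in 20. The gap to the nearest library, as a share of the group's range, was 0.791 for Itgal, lowest in WT 7, and 0.656 for Lrba, lowest in WT 8. It was 0.677 for Arl4c, lowest in cKO 1, and 0.779 for Eed, lowest in cKO 3. It was 0.658 for Hspa1a, highest in WT 8, and 0.651 for Vegfa, highest in WT 10. The mean of the nuclear oxidative phosphorylation genes was lowest in WT 10 with 0.764, and total counts were highest in WT 7 with 0.689, at 26296071 against 22226672 for the next WT library.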

How the results depend on the processing

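Fits without cKO 1 and cKO 2, with weights per group and with library totals without Apoe, and the permutation of list means, were chosen after the data had been seen. None of the 882 called genes changed sign in any of the 22 other fits that tested it. Genes changed, higher and lower moved to 2385, 1219 and 1166 with a surrogate variable, to 1802, 963 and 839 by DESeq2, to 4638, 2505 and 2133 with limma-voom sample weights, and to 416, 141 and 275 without cKO 1 and cKO 2. Without single libraries they ran from 460 to 2818, from 151 to 1633 and from 309 to 1185. The cause of these moves was not tested. Counts were 896 with RLE scaling, 728 with no filter, 644 with a mean of at least 5 CPM, 966 with the CNS component (500 of them among the 882), 854 with weights per group and 723 with library totals without Apoe, which leaves out both Apoe and TMM. Kdm6a passed with the CNS component (-1.26), the surrogate variable (-0.91) and sample weights (-0.58), ran from -0.89 to -0.58 without single libraries, and had no value under the filter of 5 CPM.

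Lists called were 20 with sample weights, 0 with an estimated correlation in camera (2 under an unadjusted p of 0.05), 4 with fry and 3 by permutation of means, and 10 to 14 without single libraries. Lists of other cell types called were 2 with RLE scaling, 2 without cKO 1 and cKO 2, and 0 to 5 without single libraries. With the CNS component, log2 fold changes reversed for Lpl (0.14), Tyrobp (0.014), P2ry13 (-0.20), Cx3cr1 (-0.11), Tmem119 (-0.45), Slc1a2 (-0.034), Prx (-0.070) and Rpl22 (0.12), and list directions for astrocyte (median -0.070), homeostatic (-0.039), MHC class I (0.16) and ribosomal genes (0.011). Tmem119 reversed with the surrogate variable (-0.11), without cKO 2 (-0.021, the lowest without single libraries, where the highest was 0.28) and without cKO 1 and cKO 2 (-0.13), as did the log2 fold changes of Prx (-0.068) and Rpl22 (0.026) and the MHC class I median (0.073) in the last fit. None of these genes had passed, and the cause was not tested. Of the 77 named genes that were called, 29 lost their call with the CNS component and 29 without cKO 1 and cKO 2, against 2 with RLE scaling and 0 by DESeq2. The lost genes had a median of 77.4% and 86.3% of their log2 fold change left in the first 2 fits. The 5.88% false calls and 61.2% recovery at 2-fold come from simulated data with the same dispersion in both groups. They limit what smaller changes show at this depth but do not give the false-call rate of this comparison.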

Other observations

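The tests of the sterol lists and of the stress genes, every fit without cKO 1 and cKO 2, and the tests around Kdm6a in fits other than that of all libraries were chosen only after the results had been seen; the other tests of genome position were planned.

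Genes of TGF-beta signalling, a pathway that maintains microglia, moved both ways in cKO. Of 22 measured, 2 rose, 2 fell and 18 did not pass (3 rose and 3 fell when adjusted over the list alone). The ligand Tgfb2 rose by 2.51 ± 0.48 and the co-receptor Eng, which overlaps Fpgs, by 0.43 ± 0.09 (SE, n = 6 each), while the receptor Acvrl1 fell by 1.07 ± 0.13 and the inhibitory Smad6 by 0.72 ± 0.15. Of 20 Kdm6, Polycomb and COMPASS genes, Eed, a core subunit of Polycomb repressive complex, rose by 0.53 ± 0.09, and 19 did not pass. Of 15 genes of alternative activation and trophic support, the growth factor Vegfa rose by 1.10 ± 0.28 and Gas6, a ligand of phagocytic receptors, fell by 1.04 ± 0.22. Of 44 cytokine and NF-kB genes, the chemokine Ccl9 rose by 1.17 ± 0.28, Saa3 and the costimulator Cd80 fell (Cd80 by 1.32 ± 0.28), and 41 did not pass. None of these 4 lists passed camera (adjusted p = 0.808, 0.639, 0.317 and 0.396). The median of the TGF-beta list was 0.03 and that of the cytokine list 0.03, while camera pointed down in both. Vegfa passed in 3 and Ccl9 in 6 of the 12 fits without 1 library (both were lost without cKO 1 or WT 7, 8, 9, 11 or 12, and Vegfa also without cKO 2, 3 or 4), and Eng was lost without WT 12. Vegfa and Gas6 did not pass with the CNS marker component (0.72 ± 0.28 and -0.94 ± 0.27), neither they nor Eng passed without cKO 1 and cKO 2 together (0.87 ± 0.30, -0.96 ± 0.25 and 0.44 ± 0.11), and Saa3 and Ccl9 did not pass with no filter.

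Stress and energy genes showed single changes. Of 28 immediate-early and stress genes, 3 rose, 1 fell and 24 did not pass: the heat-shock chaperones Hspa1a (3.17 ± 0.64) and Hspa1b (3.28 ± 0.38), paralogs that share reads, and Dnajb1 (0.52 ± 0.13) rose, and Ier5 fell by 0.41 ± 0.11. Among 23 unfolded protein response genes the sensor Ern1 fell by 0.45 ± 0.11, among 23 glycolysis and hypoxia genes Vegfa rose, and among 13 genes that escape X inactivation Utp14a fell by 0.35 ± 0.09. Among 74 nuclear subunits of oxidative phosphorylation Atp5g1, which has pseudogene copies, rose by 0.55 ± 0.15. No call was made by edgeR among 7 mitochondrial subunits, 33 cell cycle genes and 31 proteasome genes (0, 0 and 2 under an unadjusted p of 0.05; 0 in each by DESeq2), nor for Rpl22 (-0.13 ± 0.16, adjusted p = 0.710) and Tmem119, the RiboTag and Cre loci. Camera adjusted p were 0.534 for stress genes, 0.639 for the unfolded protein response, 0.534 for glycolysis, 0.555 for escape genes, 0.509 and 0.248 for nuclear and mitochondrial subunits, 0.591 for the cell cycle and 0.0625 for the proteasome. The nuclear subunits had a median of 0.02 while camera pointed down, and endothelial (median 0.19, mean 0.08, camera down) and monocyte markers (median -0.13, mean 0.05, camera down) also differed in sign. Dnajb1, Ier5, Atp5g1 and Utp14a passed in 3, 3, 4 and 1 of the 12 fits without 1 library. All 4 were lost without cKO 4 or WT 7, 8, 9, 11 or 12. Dnajb1 was lost also without cKO 1 or 3 or WT 10, Ier5 without cKO 1, 2 or 3, Atp5g1 without cKO 2 or 6, and Utp14a in every such fit except that without cKO 5. Ern1 was lost without cKO 1 or WT 8, 9 or 10. Ier5, Atp5g1 and Utp14a did not pass with the CNS marker component (-0.31 ± 0.11, 0.54 ± 0.16 and -0.32 ± 0.11), and neither they nor Ern1 passed without cKO 1 and cKO 2 together (-0.32 ± 0.11, 0.56 ± 0.16, -0.34 ± 0.11 and -0.47 ± 0.12). Calls also ended with no filter for Dnajb1, Ier5, Atp5g1 and Utp14a, with library totals without Apoe for Ier5, Ern1 and Utp14a, with weights per group for Atp5g1 and Utp14a, and with RLE scaling or a minimum mean of 5 CPM for Utp14a.

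Lower sterol sensing in cKO microglia could be asked about from the higher cholesterol synthesis mean and the lower LXR target mean, but it was not tested here. The per-library difference of the list means was -2.13 ± 0.47 in cKO and -3.29 ± 0.22 in WT (SD, n = 6 each), and the groups differed by 1.16 (exact permutation p = 0.00216, the smallest possible). Without cKO 1 and cKO 2 they differed by 1.04, with an exact permutation p of 0.00476, the smallest that 4 against 6 can give. Each list mean had already been seen to separate the groups, so these values describe the pattern and do not bear on its cause. The lists share 0 members.

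Higher Hspa1a and Hspa1b might come from handling that differed between the groups. Of the 23 immediate-early genes other than heat-shock genes, 0% rose and 1 fell in edgeR (list mean exact permutation p = 0.766), but their log2 fold changes went both ways, 13 of the 23 being positive, so these genes leave handling open.

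Variants linked to the floxed allele could differ between the groups near Kdm6a, and whether called genes were more frequent there stays open. Within 10 Mb, 7 of 50 tested genes were called (14% against 5.86% elsewhere, a ratio of 2.39, Fisher's exact p = 0.0262): Tspan7 and Mid1ip1 fell, and Maoa, Cask, Klhl13, Syn1 and Chst7 rose, named after their values had been seen. Mid1ip1, Klhl13 and Syn1 passed in 4, 3 and 3 of the 12 fits without 1 library (highest adjusted p 0.0938, 0.103 and 0.102), and the other 4 in all 12. The higher frequency itself had a Fisher's exact p under 0.05 only in the fits without WT 8 and without WT 10, with p from 0.0261 to 0.141 and ratios from 1.58 to 2.63 over the 12. Syn1 is a neuronal gene. Without cKO 1 and cKO 2 the ratio was 2.18 with 3 genes called (Fisher's exact p = 0.159). With the CNS marker component the ratio was also 2.18, with 7 genes called (Fisher's exact p = 0.0404), 5 of them among the first 7, as Klhl13 and Syn1 gave way to Gm14493 and Uxt. Effects of the deletion on its neighbours were not separated from linked variants. Over 262 bins of 10 Mb across the genome, the smallest adjusted p was 0.372. The bins of smallest p, on chromosome 11 from 110 to 120 Mb (17 of 129 genes called, p = 0.00148) and from 60 to 70 Mb (17 of 137, p = 0.00284) and on chromosome 3 from 80 to 90 Mb (14 of 109, p = 0.00473), had smaller unadjusted exact p than the Kdm6a window. The bin from 10 to 20 Mb on X, where Kdm6a lies, had 4 of 24 genes called and an adjusted p of 1. No bin passed, but a bin of the median size of 44 genes would have needed 10 called (22.7%, or 3.86 times the share of all genes), so linked regions with fewer called genes stay open.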
